A study of Mus musculus with 6 samples.

How the data were processed

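Gene expression was measured in mouse colon on Illumina bead arrays, with 1 array for each of 6 samples. Per the labels, 3 samples came from control mice and 3 from knockout (KO) mice of the C57BL/6 background aged 6 weeks, and the series concerns disruption of Setd2. The labels do not say whether the deletion was restricted to a cell type, nor how it was made. Per the labels' protocols, total RNA was taken up in Trizol, purified on Qiagen columns with DNase I, checked on a Bioanalyser and amplified into biotinylated cRNA with an Ambion kit.

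The values used were the authors' deposited probe intensities on a linear scale, 45281 probes on each array. The software, background correction and version behind them are not given in the sources used here. In the deposited intensities all 6 arrays share 1 median (3.82) and 1 maximum (16715), as quantile normalization gives, and the lowest value is exactly 1. Probes at this floor of 1 made up 33.5% to 36.9% of the probes on 5 arrays and 41.6% on control 2. A value at the floor has no order against other such values, so a difference between a group at the floor and another group is no fold change. Because the arrays already share 1 median and 1 maximum, an effect that shifted most genes one way cannot be read from these values. Below the median they differ in the share of probes at the floor. A further table of unnormalized values with detection p-values was not used here, because the names of its 12 columns match none of the samples' labels. The series' processed values took its place, as the plan fixed before the data were examined allowed for.

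Intensities were log2 transformed with no offset and no further normalization. Probes were named through the platform annotation supplied with the data: 34885 probes had 1 gene symbol, 18 had several and 10378 had none. Of the 19057 Entrez identifiers among them, 18992 were found in the RefSeq gene table for GRCm38.p6, and 0 symbols needed an update. That table was used only for names and for which genes neighbour each other, since the files name no genome build. Probes with a mean log2 value above the 40th percentile of all probes (0.96) were kept, 27168 in all. Each gene was represented by its probe with the highest mean, and unnamed probes stayed in as features of their own. This left 18918 features, 14530 of them named.

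KO was compared with control in limma 3.58.1 (R 4.3.3) with lmFit and eBayes without trend or robust options, 2-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Log2 differences are KO minus control throughout. Errors beside means are SDs over the 3 arrays of a group, and errors of differences are limma's standard errors. The number of arrays limits the precision: an exact permutation test of 3 against 3 values cannot go below p = 0.1. Gene lists for cell types, pathways and signs of neighbouring tissue, 39 lists with 1128 genes, were fixed before the data were examined. The 38 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Beside it stood camera with an estimated correlation, which allows for genes of a list moving together, and fry. The list of sex-linked transcripts had 4 measured genes and was not tested.

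The fit was tested on simulated data for KO against control, with 18918 features, 200 of them changed, in 5 runs per size of change. The changed features were drawn only from those well above the floor, and the simulated values had no floor. The recovery rates that follow therefore do not cover dimmer features. A log2 change of 3 was recovered in 57.3% of changed features with 32 false calls over the 5 runs, while log2 changes of 1 and 2 were recovered in 0% at the adjusted threshold. At an unadjusted p under 0.05, 57.9%, 89.4% and 95.0% of features changed by 1, 2 and 3 were found. In the simulated data each gene was drawn independently of the others. Before any shift was added, camera made 0 false calls over the 38 lists in 20 runs. A shift of 0.5 in the smooth muscle list was found by camera with the preset correlation in 13 of 20 runs. With an estimated correlation it was found in 0 of 20. In the real data the estimated correlation was 0.37 for smooth muscle genes and 0.50 for interferon genes. The 0 false calls therefore do not give the error rate there.

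The genes named were fixed by a rule before the data were examined: Setd2, the 12 genes per direction with the largest change among those past the threshold whose groups do not overlap, or the 8 with the smallest p where fewer than 8 pass, and up to 4 members with the smallest p in each list called or discussed. Genes with only a clone name were skipped in the top lists, 1 among those higher and 2 among those lower. A second rule was added after the values were seen, since most genes named by the first lay near the floor: the 10 genes per direction with the smallest p among features with a mean log2 value above the 70th percentile of all probes (3.92). All probes of each named gene were compared. Alternatives tried were no filter, the mean of a gene's probes, every probe on its own, other eBayes options, array weights, the replicate number as a block, sex as a covariate, other thresholds, other set tests and leaving out each array. Added after seeing the data were an offset of 16 before log2, the higher filter, these 2 together with and without control 2, the mean of pancreatic acinar genes as a covariate, and sex as a covariate without control 2. Plots were drawn with matplotlib 3.10.9 (Python 3.11.15).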

Results

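Colon RNA from 3 control and 3 Setd2 KO samples was profiled to find genes misregulated in this tissue when Setd2 is disrupted. Setd2 encodes the histone methyltransferase that trimethylates lysine 36 of histone H3. Each array reported 45281 probes, of which 8733 had a normalized intensity over 64. The labels describe the samples as replicates without stating that each came from a different animal, so p-values measure the spread between these samples.

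In KO colon the brightest Setd2 probe gave 35.7% of its control signal. Genes for glutathione and antioxidant metabolism, drug and steroid metabolism, smooth muscle, absorptive colonocytes and hormone-producing cells were called higher in KO as groups. Interferon-stimulated and antigen-presentation genes were called lower. All these group calls were lost when the correlation between genes was estimated from the arrays. In simulated data with independent genes, that test found a shifted list in 0 of 20 runs. A call lost there need not reflect genes moving together. Of the called lists, however, only the glutathione and antioxidant list had an estimated correlation (0.0098) no higher than the preset 0.01. For the other called lists it lay between 0.033 (enteroendocrine markers) and 0.50 (interferon and MHC genes), with 0.37 for smooth muscle, 0.31 for small intestinal and 0.17 for fibroblast genes. All calls but that of the glutathione and antioxidant genes were also lost without at least 1 of the arrays. For every called list the means of single arrays overlapped between control and KO. Splits of the arrays into 3 and 3 other than by genotype gave 1 to 8 called lists, against 9 by genotype. No single gene passed the adjusted threshold, and the list of T and NK cell genes did not pass.

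The brightest Setd2 probe (ILMN_2682936) had intensities of 374, 600 and 329 on the control arrays and 201, 119 and 146 on the KO arrays. The means were 434 ± 145 (SD, n = 3) in control and 155 ± 41.9 (SD, n = 3) in KO, so KO retained 35.7% of the control signal. The log2 difference was -1.47 with a standard error of 0.44 (limma adjusted p = 0.786), and all 3 KO arrays lay below all 3 control arrays (exact permutation p = 0.1, the smallest possible). The other 2 Setd2 probes were dim. One differed by -0.64. The other measured 38.0 and 31.2 on control 1 and control 3 and 6.60 to 15.7 on the KO arrays, with control 2 at the floor of 1. Without control 2 the log2 differences of the bright probe and of these 2 probes were -1.21, -0.93 and -1.72. Where these probes lie relative to the deleted part of the gene is not known, so they check the labels only in part.

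**Figure D1:**
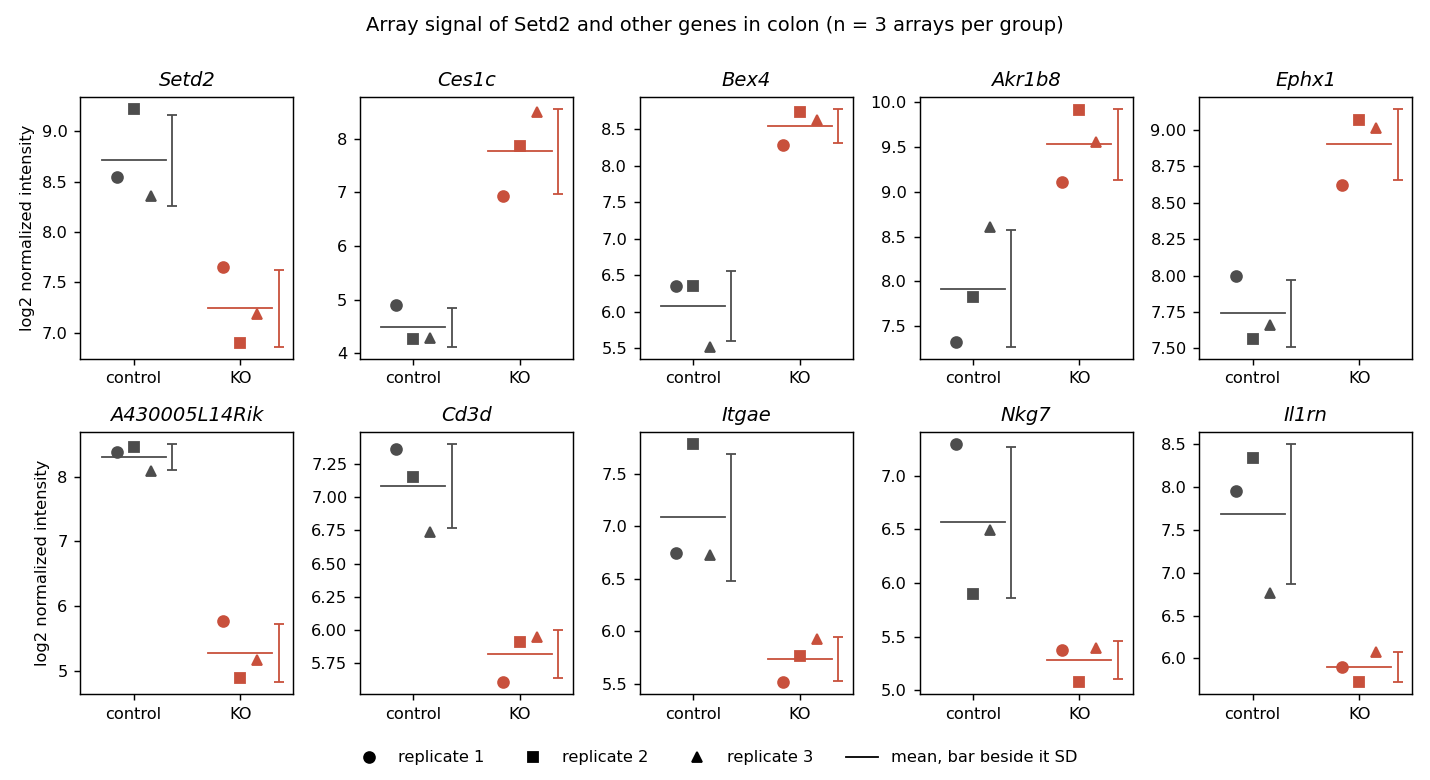
Log2 normalized intensity of Setd2 and 9 other genes on the 3 control and 3 KO arrays, with the group mean as a line and the SD as a bar beside it. For each of these genes the groups do not overlap: Setd2 lies between 8.36 and 9.23 on control arrays and between 6.89 and 7.65 on KO arrays, yet no gene passed the adjusted threshold. The 9 other genes were picked for their small p, so that little overlap follows from the choice. Over all features the groups did not overlap for 8.68%, against 10% by chance.

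In limma, 0 of 18918 features passed an adjusted p of 0.05, and the smallest adjusted p was 0.400. At an unadjusted p under 0.05 there were 814 features, 314 higher and 500 lower in KO, where chance alone would give 945.9. Groups did not overlap for 1643 features, or 8.68%, against 10% by chance. On simulated data of this size, with changes placed only in features well above the floor, no log2 change of 2 or less was recovered after adjustment. Changes of that size were thus not detectable gene by gene among such features.

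None of the 8 genes with the smallest p in each direction passed, where genes with only a clone name were skipped, and all but Ces1c lay near the floor. Vmn1r30, Hnrnpa3, Trim30b, Gh, Adcy7, Amer3 and Spata3 were listed at the floor on all 3 control arrays, with KO means of 2.16 to 3.03 on the log2 scale. Depdc1a, Ripply1, Olfr979, Ccr9 and Olfr8 were listed at the floor on all 3 KO arrays, and Mak, Dio3 and Vmn1r36 on 1 or 2 of them, with control means of 2.38 to 3.23. Other probes of Hnrnpa3, Adcy7, Amer3, Spata3, Vmn1r30 and Depdc1a went the other way in at least 1 case each, all near the floor. The exception was Ces1c, a carboxylesterase, which measured 4.49 ± 0.36 (SD, n = 3) in control and 7.77 ± 0.80 in KO, a log2 difference of 3.28 (SE 0.53, adjusted p = 0.400). A second probe was listed at the floor on control 2 and control 3 and was higher in KO, and the third was near the floor in both groups.

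Among the brighter genes, chosen after the values were seen, those higher in KO with the smallest p were Ces1c, Bex4, Ghrl, Ak4, Slc27a2, Akr1b8, Pcbp3, Castor2, Pnkd and Ephx1. Bex4 measured 6.08 ± 0.48 (SD, n = 3) in control and 8.54 ± 0.24 in KO, and its 2 other probes differed by 1.77 and 0.97. Ghrl, which encodes the hormone ghrelin, differed by 2.08 on one probe and 2.27 on the other. Ak4, a mitochondrial adenylate kinase, differed by 2.68 (SE 0.77), and Slc27a2, which activates very long chain fatty acids, by 1.56 and 1.77 on its 2 probes. Pcbp3 differed by 1.25, Castor2 by 1.41 and Pnkd by 1.31. For Pnkd both dimmer probes, near the floor, went the other way.

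Those lower in KO were A430005L14Rik, Spdl1, Krt84, Zfp954, Ceacam10, Traf1, Clec2e, Sh2d2a, Gpr171 and Il1rn. The uncharacterised A430005L14Rik had the clearest separation, 8.31 ± 0.20 (SD, n = 3) in control against 5.27 ± 0.45 in KO, and its second bright probe differed by -2.51. Its other 2 probes had lower means in KO too, although control 2 was at the floor for both. Spdl1, a kinetochore protein, differed by -2.49 (SE 0.46), the hair keratin Krt84 by -2.10, the zinc finger gene Zfp954 by -2.14 and Ceacam10 by -1.90. Traf1, an adaptor of TNF receptors, differed by -2.21 and -1.69 on its 2 probes, and Il1rn, the interleukin-1 receptor antagonist, by -1.78. Clec2e, Sh2d2a and Gpr171 differed by -1.81, -1.68 and -1.83. Sh2d2a encodes an adaptor protein of T cells. The limma adjusted p of these genes lay between 0.400 and 0.917, and 101 of 10308 features this bright had an unadjusted p under 0.05 against 515.4 by chance. When the 10308 features were fitted alone, without the dimmer ones, this count was 202.

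Of 35 measured genes for NRF2, glutathione and antioxidant metabolism, 25 were higher and 10 lower in KO, with a median log2 difference of 0.20 and a mean of 0.53. Camera called the list higher (adjusted p = 0.0071), but adjusted p = 0.625 with an estimated correlation. The correlation estimated for this list was 0.0098, against the preset 0.01, so genes moving together do not account for that loss. Akr1b8, an aldo-keto reductase, measured 7.92 ± 0.65 (SD, n = 3) in control and 9.53 ± 0.40 in KO. Ephx1, the microsomal epoxide hydrolase, measured 7.74 ± 0.23 and 8.90 ± 0.25. The glutathione transferases Gstp1 and Gsta2 differed by 1.21 and 0.97, with Gstp1 lowest on control 2 (8.72 against 10.56 and 10.84 on the other control arrays). Without control 2 they differed by 0.55 and 0.58. This call held without each of the 6 arrays in turn, at adjusted p between 0.0047 and 0.0479, but its size moved. The median was 0.38 without control 3, 0.32 without KO 2 and 0.31 without control 1, and the list mean was 6.98 on control 2 against 7.72 to 8.23 on the other 5 arrays.

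Of 42 genes for xenobiotic and steroid metabolism, 30 were higher, with a median difference of 0.48 (camera adjusted p = 0.0171, but adjusted p = 0.660 with an estimated correlation). The sulfotransferase Sult1a1 measured 10.15 ± 0.43 (SD, n = 3) in control and 10.95 ± 0.60 in KO. The other 3 genes of smallest p lay near the floor: the efflux pump Abcc2 was listed at the floor on 2 control arrays and between 1.69 and 5.03 in KO, Hsd3b3 was at the floor on 2 control arrays, and Ugt2b5 was listed at the floor on all KO arrays. The list mean was highest on KO 1 (6.91, against 6.16 and 5.98 on the other KO arrays), and the call was lost without KO 1 (median 0.32, adjusted p = 0.253) or control 1 (median 0.19, adjusted p = 0.442).

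Of 22 smooth muscle genes, 20 were higher in KO, with a median difference of 0.30 and a mean of 0.58 (camera adjusted p = 0.0071, but adjusted p = 0.720 with an estimated correlation). Smooth muscle myosin heavy chain, Myh11, measured 8.94 ± 2.41 (SD, n = 3) in control and 11.03 ± 0.14 in KO, and the regulatory light chain Myl9 8.96 ± 2.51 and 11.10 ± 0.27. Both control SDs came from control 2, where Myh11 was 6.17 against 10.01 and 10.63, and without it Myh11 differed by 0.70 and Myl9 by 0.71. Filamin A, Flna, differed by 1.49 (0.84 without control 2), and Ppp1r12b was near the floor, with control 2 at it. The call was lost without control 1 (median 0.0072, adjusted p = 0.293), KO 2 (median 0.17, adjusted p = 0.0542) or KO 3 (median 0.18, adjusted p = 0.103). It held without control 2 (median 0.64, adjusted p = 7.8e-05) and without KO 1 (median 0.61, adjusted p = 4.4e-05). Fibroblast and matrix genes were higher for 20 of 31, with a median of 0.25 (camera adjusted p = 0.0335, but adjusted p = 0.720 with an estimated correlation). The proteoglycan Lum measured 3.58 ± 1.69 in control and 5.46 ± 0.99 in KO, fibronectin (Fn1) 5.18 ± 2.49 and 7.27 ± 0.37, and Mgp 7.83 ± 0.65 and 8.70 ± 0.44. Without control 2 these 3 differed by 1.04, 0.67 and 0.57. Lox was at the floor on control 2 and control 3. This call was lost without control 1 (median 0.056, adjusted p = 0.328), KO 2 (median 0.0064, adjusted p = 0.278) or KO 3 (median 0.18, adjusted p = 0.105), and the median was 0.47 without KO 1.

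Among absorptive colonocyte markers 21 of 24 were higher in KO, with a median difference of 0.42 (camera adjusted p = 0.0130, but adjusted p = 0.625 with an estimated correlation). Carbonic anhydrase 1, Car1, measured 8.85, 8.11 and 13.68 on the control arrays and 13.43, 13.73 and 13.38 on the KO arrays. The water channel Aqp8 measured 9.83 ± 1.72 (SD, n = 3) in control and 11.86 ± 0.45 in KO. Dhrs9 was higher and Slc6a14 lower near the floor, with control 2 at it for Dhrs9 and KO 1 and KO 3 for Slc6a14. The list call was lost without control 2, where the median was 0.17 (adjusted p = 0.145). It was also lost without control 1 (adjusted p = 0.114), KO 1 (adjusted p = 0.101) or KO 2 (adjusted p = 0.0542), where the medians were 0.64, 0.45 and 0.50. Small intestinal enterocyte markers were higher for 17 of 22, with a median of 0.85 (camera adjusted p = 0.0445, but adjusted p = 0.792 with an estimated correlation). Their mean was 6.66 on KO 1 and between 3.27 and 4.88 on the other 5 arrays. The aminopeptidase Anpep was 8.41 on KO 1 against 5.26 and 5.85 on the other KO arrays, the amino acid transporter Slc6a19 6.52 against 4.21 and 3.36, and Apob 7.48 against 4.31 and 4.79, while Fabp1 was at the floor on all KO arrays. Without control 2, Anpep and Apob differed by 0.89 and 0.83 in place of 1.71 and 2.39. Without KO 1 the median was -0.05 (adjusted p = 0.878), and the call was also lost without control 1 (median 0.41, adjusted p = 0.640) or control 3 (median 0.87, adjusted p = 0.0821).

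Of 23 enteroendocrine markers, 17 were higher in KO, with a median difference of 0.40 (camera adjusted p = 0.0380, but adjusted p = 0.625 with an estimated correlation). Neurog3, the transcription factor that specifies hormone-producing cells, measured 3.84 ± 0.76 (SD, n = 3) in control and 5.36 ± 0.69 in KO. Carboxypeptidase E, Cpe, measured 8.11 ± 1.88 and 9.74 ± 0.18, with control 2 at 5.94, and differed by 0.55 without it. The granin family gene Scg3 differed by 1.84 (1.06 without control 2), and Pax4 was higher with 2 control arrays at the floor. This call was lost without control 1 (median 0.22, adjusted p = 0.433), KO 2 (median 0.38, adjusted p = 0.261) or KO 3 (median 0.38, adjusted p = 0.0848). Of 49 splicing factor genes, 34 were higher, with a median of 0.18 (camera adjusted p = 0.0335, but adjusted p = 0.660 with an estimated correlation). The leading members did not share that direction: Rbm25 and Srsf3 differed by -1.65 and -0.68, U2af1 and Hnrnpa2b1 by 1.18 and 1.66 (0.31 and 0.59 without control 2), and 2 dimmer Hnrnpa2b1 probes by -0.58 and -0.85. The list mean was 6.45 on control 2 and between 7.45 and 7.73 on the other 5 arrays. Without control 2 the call was lost (median 0.094, adjusted p = 0.615), as it was without KO 1 (median 0.26, adjusted p = 0.106) or KO 2 (median 0.21, adjusted p = 0.0737). The call held without control 1, control 3 or KO 3, with medians of 0.34, 0.28 and 0.33 (camera adjusted p between 0.0135 and 0.0479).

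**Figure D2:**
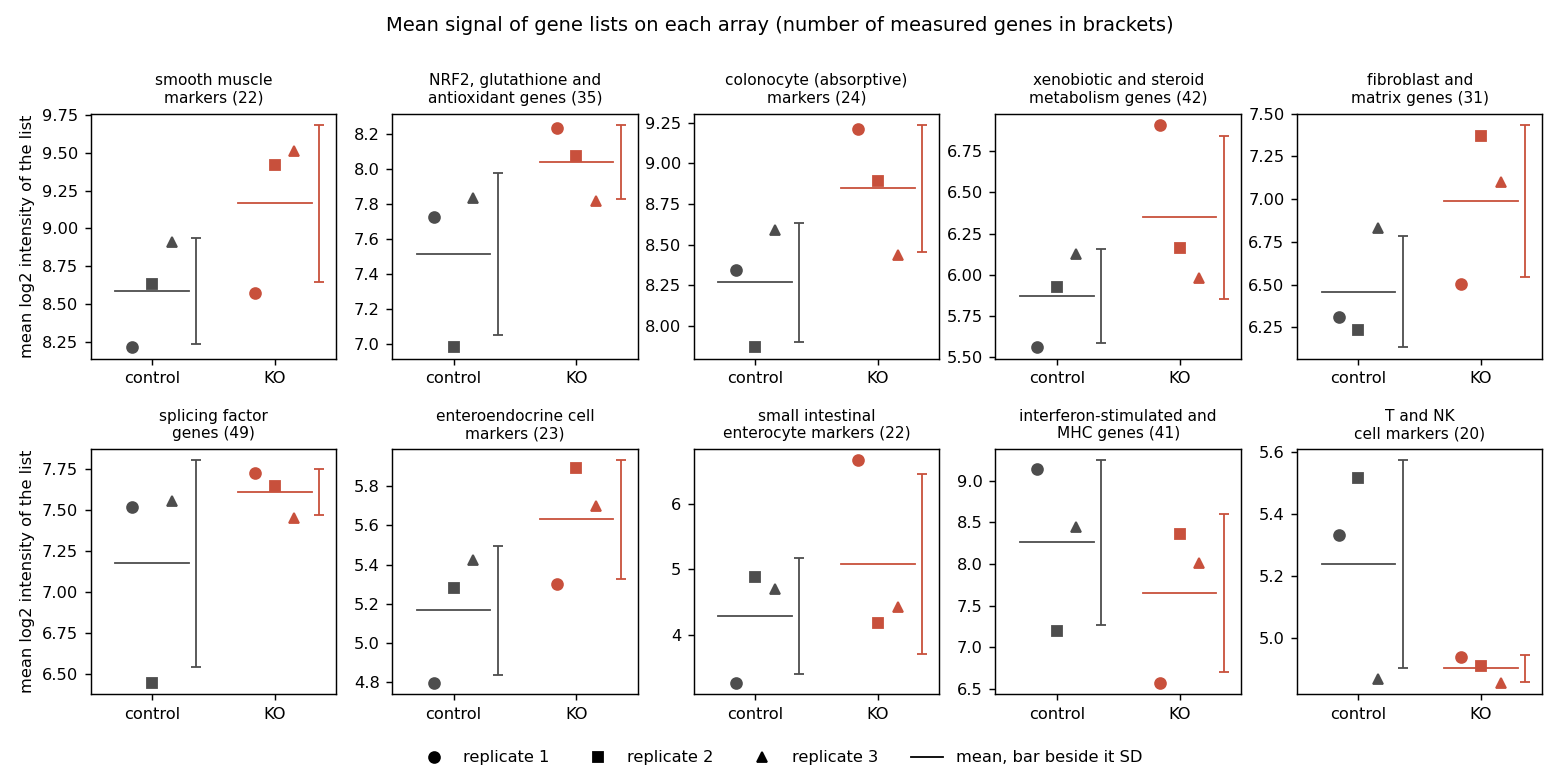
Mean log2 normalized intensity of 10 gene lists on each array, with the group mean as a line and the SD as a bar beside it. For interferon-stimulated and MHC genes the highest array is control 1 (9.14) and the lowest KO 1 (6.57), and for splicing factor genes control 2 (6.45) lies apart from the other 5 arrays.

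Of 41 interferon-stimulated and MHC genes, 35 were lower in KO, with a median difference of -0.75 and a mean of -0.61 (camera adjusted p = 0.0071, but adjusted p = 0.800 with an estimated correlation). The interferon-inducible GTPases Irgm1 and Mx2 measured 11.63 ± 0.24 (SD, n = 3) and 7.04 ± 0.67 in control and 10.88 ± 0.24 and 5.21 ± 1.45 in KO. Iigp1, another such GTPase, measured 5.16, 4.27 and 4.12 on the control arrays and 3.87 and 1.86 on KO 2 and KO 3, with KO 1 at the floor, and Ifit3, an antiviral RNA-binding protein, measured 10.57 ± 1.15 and 8.64 ± 1.75. Without KO 1, Mx2 and Ifit3 differed by -1.02 and -0.92 in place of -1.84 and -1.93. The list mean was 9.14, 7.19 and 8.45 on the control arrays and 6.57, 8.36 and 8.02 on the KO arrays. The call was lost without KO 1 (median -0.15, adjusted p = 0.550), control 1 (median -0.27, adjusted p = 0.640) or control 3 (median -0.71, adjusted p = 0.0837), and held without control 2 (median -1.05, adjusted p = 1.4e-09).

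Of 20 T and NK cell markers, 15 were lower, with a median of -0.54, and the list did not pass (camera adjusted p = 0.0659, and adjusted p = 0.660 with an estimated correlation). The median was -0.17 without control 2, -0.33 without KO 1 and -0.35 without KO 2. The list passed under 5 of 21 alternatives, 4 of them chosen after the values were seen, and its adjusted p ranged from 5.7e-06 to 0.660. The 4 members described next are those of smallest p in the list, so that little overlap between groups follows from their choice. Cd3d, a subunit of the T cell receptor complex, measured 7.09 ± 0.32 (SD, n = 3) in control and 5.82 ± 0.18 in KO. Itgae, the integrin of lymphocytes lodged in epithelium, measured 7.08 ± 0.60 and 5.74 ± 0.21, and its second bright probe differed by -1.32, while 2 dim probes went the other way. Nkg7, a cytotoxic granule gene, measured 6.56 ± 0.70 and 5.28 ± 0.18, and Cd160 6.06 ± 0.64 and 4.98 ± 0.04 (a difference of -0.70 without control 2 in place of -1.07). Of 26 inflammatory cytokines and chemokines, 19 were lower, with a median of -0.52 (camera adjusted p = 0.0659, and adjusted p = 0.625 with an estimated correlation). The chemokine Ccl4 measured 7.44 ± 0.26 (SD, n = 3) in control and 5.77 ± 0.71 in KO, Csf3 and Il22 were near the floor in KO, and Osm differed by -0.96 (-0.58 without KO 2). Without control 2 this list passed (adjusted p = 0.0116), as it did without KO 3 (adjusted p = 0.0418), and in all under 7 of 21 alternatives.

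In each of these lists 0 genes passed over all features, and in the 9 called lists 0 passed adjusted over the list alone. Fry called 0 lists. Its smallest adjusted p was 0.0989, for Wnt pathway components, a list that camera did not call.

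Array features that vary across the groups accompany these values. Control 2 correlated with the other arrays at r between 0.802 and 0.822 over the features tested, where the other 5 correlated among themselves at 0.909 to 0.937. The mean of 19 pancreatic acinar genes was 12.20, 9.81 and 3.68 on the control arrays and 9.44, 8.99 and 3.60 on the KO arrays. Xist signal was present on control 1 and KO 1, and Eif2s3y signal on the other 4 arrays, so each group held 1 sample with Xist and 2 without. Control 1 and KO 1, the samples with Xist, lay at opposite ends of the interferon list.

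**Figure D3:**
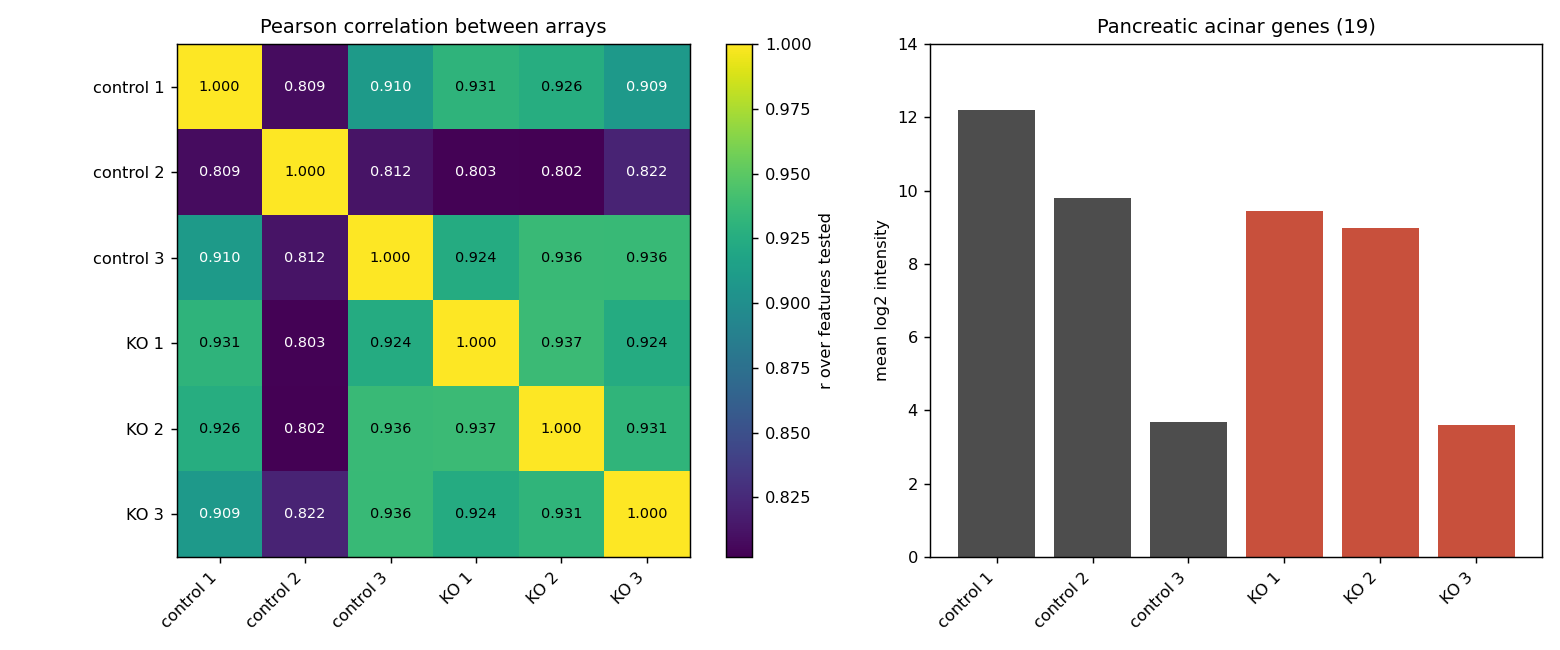
Left, Pearson correlation r between the 6 arrays over the features tested. Right, mean log2 normalized intensity of 19 pancreatic acinar genes on each array, with control in grey and KO in red. Control 2 stands apart with r of at most 0.822, and acinar signal is low on control 3 (3.68) and KO 3 (3.60).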

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

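Of 25 alternatives, 6 were chosen after seeing the data (an offset of 16, the 70th percentile filter, both together with and without control 2, the acinar mean as a covariate, and sex with control 2 left out). The count of 0 changed genes stayed 0 under every setting at an adjusted threshold except without the filter on dim probes, where 11 passed, 9 higher and 2 lower. Of these, 10 had 1 group at the floor on all 3 arrays and none exceeded 3.28 on the log2 scale, and they include Vmn1r30, Trim30b, Amer3 and Depdc1a. The 1864 features at the floor on all 6 arrays, which have no spread, enter that fit. At an unadjusted p under 0.05 and 1.5-fold there were 814, 314 higher and 500 lower. The Setd2 log2 difference lay between -1.67 and -0.71 and never passed; -0.71 was the mean of its 3 probes. The mean of a gene's probes turned Pnkd to -0.39 and Aqp4 to -0.27, since their dimmer probes go the other way. The other named genes run under these settings kept their direction.

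The 8 lists called higher became 0, and the 1 called lower became 0, both with camera's estimated correlation and with fry. Leaving out 1 array gave 2 to 8 lists higher (2 without control 1) and 0 to 3 lower. Lists called lower numbered 3 with the mean of a gene's probes, 2 with array weights, 3 with the offset, 2 with the 70th percentile filter, 2 with both, 6 with both and control 2 left out, 2 with the acinar covariate and 5 with sex and control 2 left out; the cause was not tested. For the 15 lists described in full, over the 21 alternatives that give list values, 54 fell short of the threshold that they had passed, 25 newly passed it and 236 kept their side. The test's direction reversed for 0, although the median of the small intestinal list turned from 0.85 to -0.05 without KO 1. With the replicate number as a block 0 genes passed, 8 lists were higher and 2 lower. Whether the numbers pair the samples is not settled. Deviations of same-numbered arrays correlated at 0.163, -0.094 and 0.037, and only control 1 correlated best with its own number. But Xist signal was present only on the arrays numbered 1, and the acinar mean was lowest on those numbered 3 (3.68 and 3.60).

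Not run were quantile normalization without background correction and a detection filter, which need the table not used here. Nor were a chip position block, for which no position is given, and median scaling, which moves nothing in values that share 1 median. Signal limits these results: the median SD within groups was 0.83 over all features and 0.53 over the brighter ones.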

Other observations

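Tests chosen only after the result was seen were those of pancreatic transcripts and of a sample swap for control 2, of genotype for the acinar genes, both for the interferon genes, and the count of splits for changed genes. The test of islet genes was chosen before, but the condition that left it undecided was added after its result was seen.

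Several groups outside the called lists moved little or fell just short in camera at the preset correlation. The array means of Wnt pathway components did not overlap between groups (4.76, 4.80 and 4.76 in control, 5.12, 5.14 and 4.98 in KO), unlike those of the called lists. By chance 10% of comparisons of 3 against 3 values separate in this way. Wnt pathway components were higher for 21 of 34 (median 0.35, camera adjusted p = 0.0508), led by Sfrp2, Dvl3, Wnt5b and Sfrp1, of which only Sfrp1 (5.86 ± 0.85 in control, 6.68 ± 0.23 in KO, SD, n = 3, differing by 0.39 without control 3) was well off the floor; without control 2 the list passed (adjusted p = 0.0399), while the median was 0.13 without KO 1 (adjusted p = 0.119) and 0.19 without control 1 (adjusted p = 0.207). Of 24 Wnt target genes 14 were higher (median 0.32, camera adjusted p = 0.106), and the median was 0.17 without control 1 or without KO 3. Myc was listed at the floor on all control arrays and at 2.80, 3.15 and 1.89 on the KO arrays, and passed adjusted over the list alone (limma adjusted p = 0.0224), but its other probe went the other way (-0.54). Of the next members Fzd7 differed by 0.88 (0.43 without control 2), while Wif1 and Ascl2 had control arrays at the floor. Among 18 stem cell markers 11 were higher (median 0.22, camera adjusted p = 0.106). With 1 array left out the median lay between 0.096 (without control 2) and 0.36 (without KO 2). In control and KO, Lrig1 measured 7.98 ± 1.17 and 9.08 ± 0.22, Rgmb 2.77 ± 1.49 and 4.35 ± 0.38, and Aqp4 10.24 ± 1.03 and 11.29 ± 0.62. Without control 2 these 3 differed by 0.43, 0.73 and 0.70 in place of 1.11, 1.58 and 1.06. For Rgmb, Aqp4 and Ascl2, 1 dimmer probe each went the other way. Skeletal muscle markers were lower for 10 of 15 (median -0.45, camera adjusted p = 0.0508). With 1 array left out the median lay between -0.29 (without control 2) and -0.85 (without control 3). Acta1, the actin of skeletal muscle, measured 8.40 ± 0.95 in control and 6.49 ± 1.16 in KO, and Tnni2 4.21 ± 0.97 and 3.11 ± 0.47 (differing by -0.61 without control 2). Actn3, near the floor, passed adjusted over the list alone (limma adjusted p = 0.0195), although its other 2 probes went the other way, and Atp2a1 was lower with KO 1 at the floor. Estimated correlations gave these 4 lists adjusted p of 0.625 to 0.660. Of 21 alternatives the Wnt component list passed under 7, the stem cell list under 5, the Wnt target list under 1 and the skeletal muscle list under 0.

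Of the lists that did not pass, some had medians close to 0. These were 0.11 for 45 cell cycle genes, 0.04 for 39 ribosomal protein genes, 0.03 for 44 oxidative phosphorylation genes, -0.05 for 23 goblet cell markers and -0.04 for 21 general epithelial markers, with camera adjusted p between 0.210 and 0.775. For the goblet and general epithelial lists the mean (0.10 and 0.07) and the test pointed up against these medians. Others lay lower in KO without passing: pancreatic acinar genes (17 of 19 lower, median -1.24, adjusted p = 0.202), granulocyte and mast cell markers (12 of 14 lower, median -0.51, adjusted p = 0.202), immediate early and heat shock genes (21 of 29, -0.34, 0.463), B and plasma cell markers (11 of 19, -0.33, 0.803), endothelial markers (17 of 24, -0.32, 0.624) and DNA repair genes (24 of 33, -0.30, 0.463). Genes that write, erase or read H3K36 methylation had a median of -0.12 over 26 members (adjusted p = 0.454), led by Setd2 itself, Phf19 (KO 2 at the floor), Setmar (-1.08, and -0.36 without control 2) and Nsd2 (-0.56, with 1 of its dimmer probes at 1.03). Of 26 antimicrobial and epithelial defence genes, 15 were higher and 11 lower (median 0.08, camera adjusted p = 0.501). Its members of smallest p, the lectins Reg3g and Reg3b, differed by 2.29 (SE 1.04) and 2.07 (SE 1.20), and neither passed. Reg3g differed by 1.47 without KO 3, and Reg3b by 0.84 without control 1. Nefl, a neurofilament gene near the floor, was lower in KO, with KO 1 and KO 2 at the floor, and passed adjusted over the neuron and glia list alone (limma adjusted p = 0.0364).

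Control 2 stands apart from the other arrays: it had 209 probes at the floor that exceeded an intensity of 64 on each other array, where the other arrays had 0 or 1 such probes. These belong to 164 genes, such as Gnb1 (at the floor on control 2, 9.63 or more elsewhere). The same genes had 136 other bright probes that were not themselves lost on control 2. Those deviated on control 2 by a median of -0.43 (95% bootstrap interval -0.66 to -0.07), against 0.08 for all bright named probes. Since further lost probes of a gene were left out, this median leans towards small deviations. For the 77 of them within 1 log2 unit this is consistent with signal lost at single probes of that array, but 51 were lower by more than that, down to -7.56 for Atp5pb, and only 98 of the 164 genes have such a probe, so for the others loss of the transcript stays open. Pancreatic transcripts do not account for it, since control 1 had more of them and a median correlation with the other arrays 0.101 above that of control 2. A swap with a KO sample is argued against only by the brightest Setd2 probe, which on control 2 lay 1.58 log2 units above the highest KO array. The dim Setd2 probes do not separate control 2 from KO. One was at the floor on control 2, and the other had an intensity of 5.06, within the KO range of 3.66 to 5.59. No other biological explanation was tested.

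Pancreatic acinar genes differ between arrays, except Zg16, which the goblet cell list also holds and which was 13.43 or more on each. Amy2a5, which encodes pancreatic amylase, measured 13.68, 13.85 and 5.41 on the control arrays and 13.52, 12.47 and 4.29 on the KO arrays, and Cela2a was at the floor on control 3 and KO 3 and above 11 elsewhere. Setd2 genotype is argued against as the cause of the differences between arrays, because the smaller range of the acinar mean within a genotype was 4.78 times the difference between genotypes (-1.22), but a smaller part in genes such as Clps (13.70, 13.27 and 12.45 in control, 11.93, 11.43 and 11.84 in KO) stays open. Pancreatic tissue carried over in dissection is a candidate source. Its test, whether islet genes follow the acinar genes, gave the 49.3th percentile of random lists. By the rule fixed before this result was seen, a value below the 95th percentile counts against pancreatic tissue. But 3 of the 4 measured islet genes never exceeded 3.32, and such genes can follow nothing. For that reason, added after the result was seen, this stays open. Ins2 reached 10.52 on control 1, the array with the highest acinar mean.

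The list of interferon and MHC genes was called lower in KO, but not with an estimated correlation (adjusted p = 0.800). An effect of sex shared by both groups is argued against, and each group held 1 sample with Xist. The list mean on control 1, a sample with Xist, lay 0.70 above the higher of the other control arrays. KO 1, the other such sample, had the lowest mean. On the arrays without Xist the list mean was 7.19 and 8.45 in control and 8.36 and 8.02 in KO. A genotype difference limited to samples with Xist was not tested. It would rest on 1 array per group and stays open. That KO 1 alone carries the difference may hold or not. The call was lost without KO 1 (adjusted p = 0.550, median -0.15), but also without control 1 (adjusted p = 0.640, median -0.27), so the cases cannot be told apart with 3 arrays per group. The adjusted p over the alternatives of this list ranged from 4.8e-16 to 0.800, and an effect of Setd2 genotype stays open.

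Flanking DNA of another strain around the targeted gene was tested through its neighbours. Of the 100 tested genes nearest to Setd2 on its chromosome 0 had an unadjusted p under 0.05, against 3.83% of the other 14429 named genes (Fisher's exact test, 1-sided p = 1). This gives no sign of a change shared by many neighbours. A share over 100 genes cannot exclude changes in a few of them, so that flanking DNA stays open.

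The 6 arrays can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. Of the 10 splits 1 gave as many called lists as the real one, namely the real one itself with 9. The highest other split gave 8 and the lowest 1. At an unadjusted p under 0.05 the real split gave 814 features, 6 of the 10 splits gave as many, and the highest other gave 1164. All 10 splits gave 0 changed genes, so the highest other was 0 as well.

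Some genes varied within a group far more than between groups. Osr2 measured 3.38, 11.18 and 12.21 on the control arrays and 8.12, 6.61 and 10.83 on the KO arrays. Prap1 measured 1.83, 10.77 and 10.50, then 10.02, 7.61 and 10.15. Hoxb7 measured 4.19, 9.96 and 9.67, then 6.14, 4.79 and 8.67. Control 1 was lowest for each of these 3 genes.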
